A study of Mus musculus with 14 samples.

How the data were processed

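The series measured mouse microRNAs (miRNAs) in primary lung alveolar type II cells of C57BL/6 mice, kept at 21% O2 (normoxia) or 85% O2 (hyperoxia) for 6 h or 24 h. Each of the 14 samples was hybridised to 1 single-colour Agilent miRNA array. Groups and replicate numbers were taken from the sample titles, which gave 4 arrays for normoxia at 6 h (replicates 1 to 4), 3 for hyperoxia at 6 h (replicates 2 to 4), 3 for normoxia at 24 h and 4 for hyperoxia at 24 h.

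Total RNA was extracted with the miRNeasy Mini Kit, per the labels. The labels' protocols describe Cy3 labelling by cRNA amplification, while the scanner protocol named in the file headers is one for miRNA arrays. Which of these labelled the RNA was not settled here. Per the file headers, the authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction version 10.7.3.1, the version that the submitters' processing notes also give. Per the file headers, each deposited spot intensity is on a linear scale after subtraction of background and of a spatial trend, can be negative, and was not normalised between arrays. Per the file headers, multiplicative detrending was off. Each sample had its own array and no columns of pooled samples were found. The files also hold a detection call per miRNA, flags for saturated and outlying spots, and a total gene signal that sums the probes of a miRNA and is set to 0.1 where the miRNA was not detected. The deposited value table of the series was compared with the scanner files. After matching of names, 15895 of 15904 values equalled the total gene signal within a relative tolerance of 0.001, and the other 9 held 1 in the table. The table was therefore on the linear scale of the scanner output, with no centring, and the median of each of its 14 columns was 0.1, the value given to miRNAs that were not detected. Each array stood for 1 sample, so the table had no direction to settle.

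Each array held 1136 entries, of which 1079 were mouse miRNAs and 57 were viral, read by 2889 probes with 10 to 40 spots each. Control spots and spots marked as outliers were left out, which removed 3.80% to 4.69% of the miRNA spots of an array and left at least 6 spots per probe. No spot was saturated. Spots were averaged per probe, and each miRNA was represented by its probe with the highest mean over the 14 arrays. Signals were divided by the 75th percentile of the array, taken over the 243 probes well above background on all 14 arrays, and multiplied by the mean of these percentiles, 551. A floor of 11.3 signal units (3.50 on the log2 scale) was then set, the median over arrays of the lowest scaled signal among probes well above background, and log2 was taken. Values at the floor have no order, and 116 of the tested miRNAs were at the floor on at least 1 array. Differences that involve such values understate the change, and their spread is understated too. A probe counted as well above background on an array where this held for more than 50% of its spots, and a miRNA where this held for any of its probes. Where a miRNA was above background on no array of 1 group, the fold is given as a lower bound, computed from the group means of the brighter group against the higher of the dim probe's own signal and the lowest signal above background per array. Probe positions were taken from the file headers' mapping to mouse genome build mm9. No gene annotation was used here, so exon or intron positions are not given.

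The 302 entries that the scanner software called detected on at least 3 of the 14 arrays were tested, 4 of them viral. Viral entries are not named. One limma model with a mean per group was fitted to all 14 arrays, with 10 residual degrees of freedom and a prior of 0.583 degrees of freedom. Contrasts gave hyperoxia against normoxia at each time, the difference of these effects between the times, and 24 h against 6 h at each oxygen level. Empirical Bayes moderation was used, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 302 entries of a comparison. An adjusted p under 0.05 counted as passing. Intervals are 95% confidence intervals of the fitted fold. The 21 miRNA lists were tested with limma's fry, which asks whether the members of a list move, on balance, one way and does not compare a list with other miRNAs. Adjustment was over the lists of a comparison. Camera with an estimated correlation between members was the alternative. The lists were the miR-34 and miR-449 family, p53-responsive miRNAs, oxygen-responsive (hypoxia-linked) miRNAs, inflammation and NF-kB, epithelial, mesenchymal and smooth muscle, endothelial, leukocyte, erythroid and platelet, striated muscle, the miR-17-92 and paralogue clusters, the let-7, miR-29, miR-30, miR-15 and miR-16, and miR-130 and miR-301 families, the miR-23, miR-27 and miR-24 clusters, miR-221 and miR-222, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 intron cluster, and array-strong entries whose origin as miRNAs has been questioned. The counts of detected entries per array were compared by exact two-sided permutation tests. With 4 arrays against 3 there are 35 splits, so the smallest p such a test can give is 0.0286.

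The groups, the model, the lists, most alternatives and the rule for naming miRNAs were fixed before the data were examined. The rule named, for each hyperoxia comparison, up to 12 passing miRNAs with the largest rise and up to 12 with the largest fall among those detected on every array of at least 1 group. For each comparison of times it named up to 10 each way, and for the difference of effects the 10 smallest p-values. Where fewer than 5 passed, the 10 smallest p-values were named with the statement that they did not pass. The rule also named 13 miRNAs in any case if they were detected on at least 3 arrays, among them miR-34a, miR-210, miR-21, miR-146a, miR-155, miR-200b and miR-143. miR-223-3p did not reach that detection and was not tested. In every list described, the passing members with the largest change were named. For the called miRNAs with at least 2 probes, the sign was compared between probes, and no probe went the other way.

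The file headers place the 14 arrays on 3 slides. Slide 1 held 8 arrays of all 4 groups, slide 2 held 5 arrays of all 4 groups, and slide 3 held 1 array, normoxia at 6 h replicate 2, which was also scanned on a later day. Slide was tested as a block and within slides 1 and 2. All arrays of 6 h were in the first row of their slide and all arrays of 24 h in the second row, so time and slide row cannot be told apart. No pair of arrays of a group held identical values, and their correlations over the tested entries were between 0.975 and 0.997. The number of arrays limits the precision.

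Alternatives were the percentile over all probes, quantile normalization, no scaling, normexp background correction with an offset of 50, the total gene signal, the series matrix values, the mean of all probes of a miRNA, a floor of 1, only entries detected on all 14 arrays, no filter, an intensity trend, the replicate number as a block, the slide as a block, array weights, only the compared groups in the fit, camera, probes well above background in place of the detection call, and leaving out each array in turn. Added after the data were seen were array brightness as a covariate, robust empirical Bayes, and a fit without the 3 arrays in doubt. These were normoxia at 6 h replicate 1 (negative control SD 12.8 signal units), normoxia at 6 h replicate 2 (alone on its slide) and normoxia at 24 h replicate 3 (the dimmest, with a 75th percentile of 289).

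The procedure was tested on simulated data with the real levels and spreads of the 302 entries, 60 of them changed, in 20 runs per comparison. At a log2 change of 0.5, 63% were recovered for hyperoxia at 6 h, 55.5% for hyperoxia at 24 h, 46% for the difference of effects, 57.2% for time in normoxia and 56.8% for time in hyperoxia. At a log2 change of 1, these shares were 88%, 90.0%, 76.8%, 91.2% and 90.0%. False calls made up 4.85%, 3.65%, 4.31%, 4.81% and 4.48% of the calls. The simulated values were drawn independently from normal distributions, with the smallest spreads raised to a minimum. They had no floor, no difference in array brightness, no scaling step and no correlation between miRNAs. These shares therefore do not cover errors from scaling, background or floor. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.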

Results

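Levels of miRNAs, short RNAs that pair with messenger RNAs and lower their translation or stability, were measured on 14 arrays of RNA from primary mouse alveolar type II cells. These epithelial cells of the lung make surfactant and are injured by high oxygen. The 4 groups were 21% O2 for 6 h (n = 4), 85% O2 for 6 h (n = 3), 21% O2 for 24 h (n = 3) and 85% O2 for 24 h (n = 4). The labels do not say whether replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Of the 1136 entries on an array, the software detected 18.2%, 24.2%, 23.5% and 24.6% on the arrays of normoxia at 6 h and 24.6%, 22.0% and 24.8% on those of hyperoxia at 6 h, in the order of the replicates. It detected 24.6%, 27.4% and 19.5% for normoxia at 24 h and 17.8%, 20.4%, 23% and 22.0% for hyperoxia at 24 h. The log2 of the 75th percentile signal was 9.34 ± 0.34 (SD, n = 4) in normoxia and 8.86 ± 0.24 (SD, n = 3) in hyperoxia at 6 h, and 9.27 ± 0.96 (SD, n = 3) and 8.58 ± 0.32 (SD, n = 4) at 24 h. The brightest array was thus 3.51 times as bright as the dimmest, and 174 entries were detected on all 14 arrays.

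**Figure D1:**
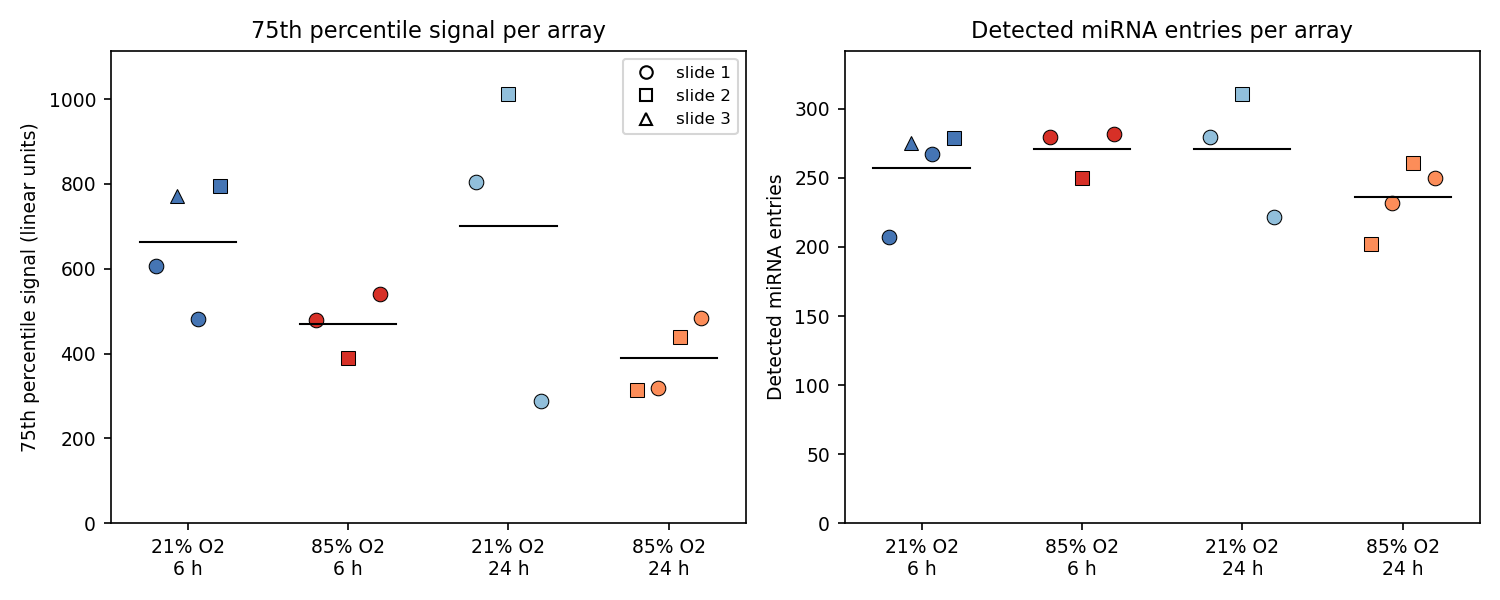
The 75th percentile signal (linear units, left) and the number of detected entries (right) of each array, by group. Each marker is 1 array with its shape giving the slide, and bars are group means; the brightest array, at 1013, and the dimmest, at 289, were both normoxia at 24 h.

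The number of detected entries did not separate the groups. At 6 h it was 257 ± 33.7 (SD, n = 4) in normoxia and 271 ± 17.9 (SD, n = 3) in hyperoxia (exact permutation test, p = 0.657, adjusted p = 0.657). At 24 h it was 271 ± 45.2 (SD, n = 3) in normoxia and 236 ± 25.8 (SD, n = 4) in hyperoxia (exact permutation test, p = 0.257, adjusted p = 0.514). Between the times the exact permutation test gave p = 0.629 in normoxia and p = 0.143 in hyperoxia. The hyperoxia arrays were dimmer by a log2 difference of -0.48 at 6 h (exact permutation test, p = 0.114) and -0.69 at 24 h (exact permutation test, p = 0.314).

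The first comparison addressed the early response to hyperoxia. After 6 h at 85% O2, miR-322-5p, a member of the miR-15 and miR-16 family, rose 2.06-fold (95% interval 1.65 to 2.57). Its log2 level went from 4.96 ± 0.28 (SD, n = 4) to 6.00 ± 0.08 (SD, n = 3), with an adjusted p of 0.00167 in limma, and its probe lies on chromosome X from 50407454 to 50407475 (mm9). miR-146a-5p, which acts in feedback on NF-kB signalling, rose 1.96-fold (1.52 to 2.52) from 5.68 ± 0.34 (SD, n = 4) to 6.65 ± 0.05 (SD, n = 3; limma, adjusted p = 0.00585; chromosome 11, 43187907 to 43187925). miR-210-3p, best known as a target of hypoxia-inducible factors, rose 1.55-fold (1.31 to 1.85) from 6.31 ± 0.19 (SD, n = 4) to 6.95 ± 0.19 (SD, n = 3; limma, adjusted p = 0.00820; chromosome 7, 148407354 to 148407369). miR-181a-5p and miR-181b-5p, processed from shared precursor transcripts and known from lymphocyte development, were the 2 miRNAs that fell, by 0.45 (SE 0.090) and 0.31 (SE 0.080) on the log2 scale. miR-181b-5p passed in 4 of 18 other settings, and its sign turned with the percentile over all probes (0.0994). Its call was lost without normoxia at 6 h replicate 1 (limma, adjusted p = 0.0753), 2 (0.0692), 3 (0.0597) or 4 (0.0535) and without hyperoxia at 6 h replicate 3 (0.0599) or 4 (0.118).

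Of the 302 entries tested, 19 passed limma's test at 6 h, 17 of them higher and 2 lower in hyperoxia. Besides those above, let-7i-5p and miR-99a-5p each rose 1.57-fold, miR-148a-3p 1.45-fold, and miR-652-3p and miR-378b each 1.41-fold. In 18 other settings miR-148a-3p passed in 9, miR-99a-5p, miR-652-3p and miR-378b in 8 each, and let-7i-5p in 7. The call of let-7i-5p was lost without normoxia at 6 h replicate 2 (limma, adjusted p = 0.0544) or 4 (0.0580) and without hyperoxia at 6 h replicate 2 (0.0766) or 3 (0.0851). That of miR-148a-3p was lost without normoxia at 6 h replicate 4 (0.0697) or hyperoxia at 6 h replicate 2 (0.0613) or 4 (0.0999). That of miR-99a-5p was lost without hyperoxia at 6 h replicate 4 (0.0579). For each of the 19 the arrays of the groups did not overlap, as for 53 of the 302 entries (17.5%), against 5.71% by chance. Among the miRNAs named in any case, miR-34a-5p, a target of p53, differed by 0.46 (SE 0.13) without passing (limma, adjusted p = 0.0555). The other such miRNAs did not pass either, with log2 differences of -0.17 for miR-34b-5p, -0.08 for miR-34c-5p, 0.31 for miR-21-5p, 0.34 for miR-155-5p, -0.10 for miR-200b-3p, -0.17 for miR-200c-3p, 0.11 for miR-143-3p and -0.09 for miR-199a-3p. miR-126-3p, an endothelial miRNA, was not well above background in either group at 6 h.

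**Figure D2:**
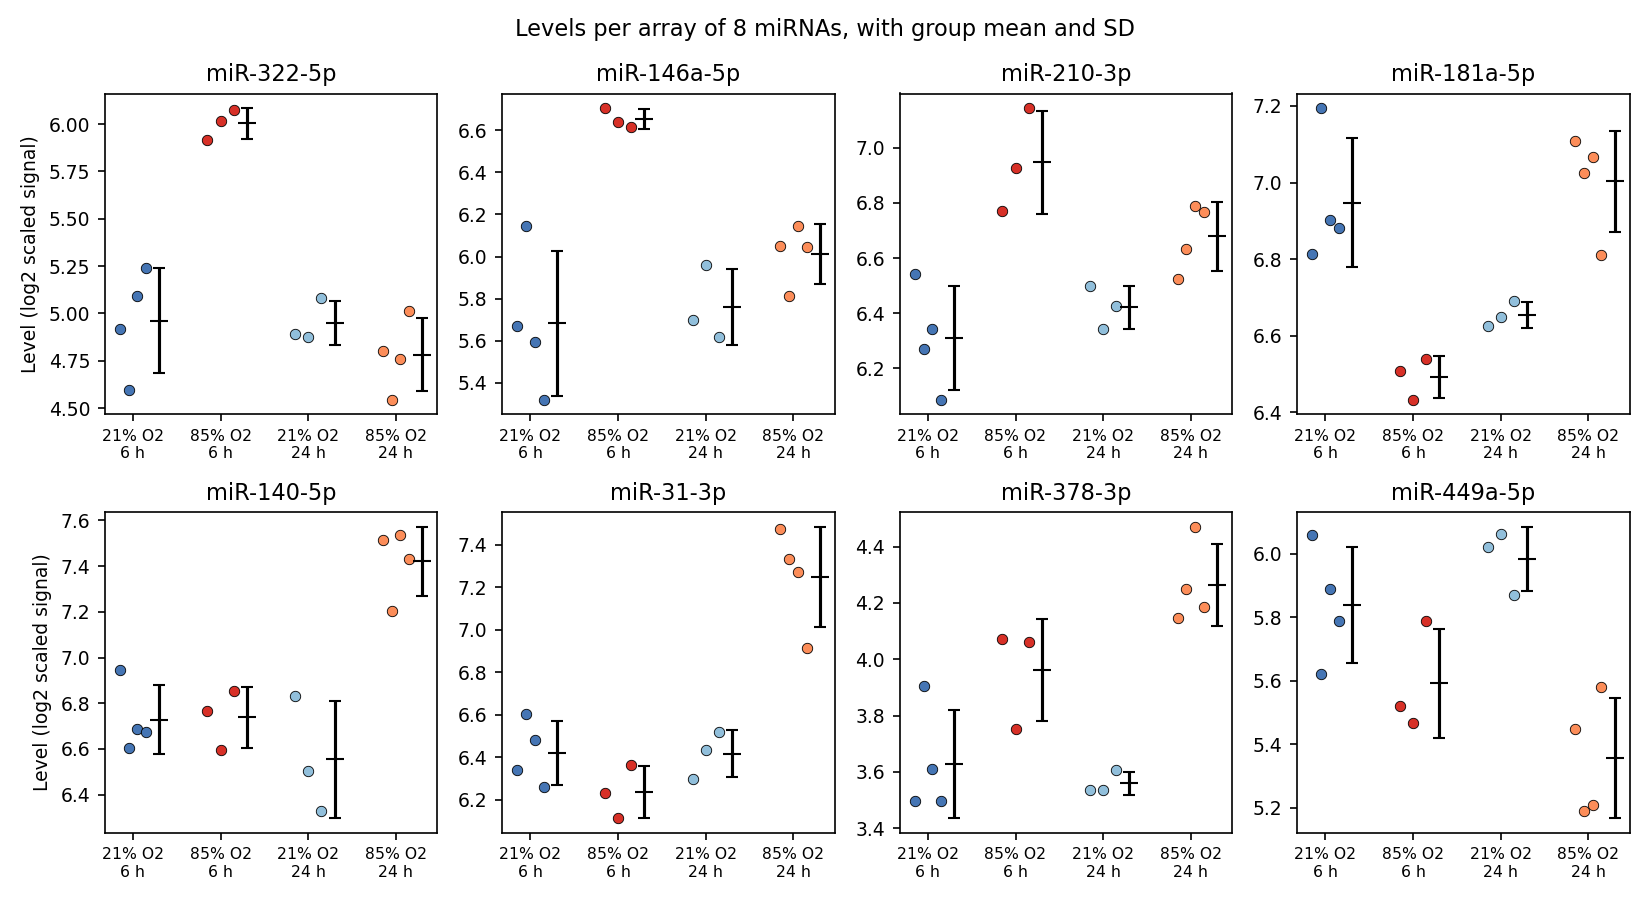
Level per array (log2 scaled signal) of 8 miRNAs in the 4 groups, with the group mean and SD beside the points; each point is 1 array and the vertical scales differ and do not start at 0. miR-322-5p, miR-146a-5p and miR-210-3p were higher at 85% O2 at 6 h, and miR-140-5p, miR-31-3p and miR-378-3p at 24 h, while miR-378-3p without scaling between arrays and miR-449a-5p with normexp background changed sign at 24 h.

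Some members of the Dlk1-Dio3 cluster, an imprinted region whose miRNAs come from the maternal chromosome, rose at 6 h. The tested members span positions 110824030 to 110981994 of chromosome 12 (mm9). Of the 24 tested, 6 rose, none fell and 18 did not pass, and 11 rose when adjusted over the list alone. miR-127-3p rose 1.66-fold (1.25 to 2.19), miR-136-5p 1.44-fold (log2 0.53, SE 0.069), miR-377-3p 1.41-fold (1.25 to 1.59) and miR-431-5p 1.36-fold (1.28 to 1.45), and 7 members were at the floor on all 14 arrays. Of the 6 called members, 3 were at the floor on all but at most 1 array of a 6 h group, among them miR-136-5p. Values at the floor have no spread, so for such members the fold depends on the floor and the SE or interval is too narrow. Over the other settings and fits the log2 difference of miR-136-5p ranged from 0.14 to 0.91. Of 17 other settings miR-377-3p passed in 8. miR-127-3p passed in 7 of 18, and its call held in 1 of 7 fits with 1 array left out. It was lost without normoxia at 6 h replicate 1 (limma, adjusted p = 0.0620), 2 (0.0692) or 4 (0.107) and without hyperoxia at 6 h replicate 2 (0.108), 3 (0.0957) or 4 (0.106). miR-541-5p, another member that rose, was above background on no normoxia array at 6 h and has no fold. The list passed limma's fry test (adjusted p = 9.80e-05, median log2 difference 0.16) but not camera (adjusted p = 0.226 with an estimated correlation). With slide as a block fry gave an adjusted p of 5.52e-04, with medians of 0.12 within slide 1 and 0.15 within slide 2. The call was lost under 9 other settings of scaling, background, summary, floor or filter, with adjusted p from 0.0950 with a floor of 1 to 0.893 without scaling, where the direction turned.

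The inflammation and NF-kB list also passed fry at 6 h with a positive direction (adjusted p = 0.00134), but not camera (adjusted p = 0.226 with an estimated correlation). Of its 6 tested members 2 rose, miR-146a-5p and miR-146b-5p (1.54-fold, 1.25 to 1.89), 4 did not pass, and 3 rose when adjusted over the list alone. The call of miR-146b-5p was lost without hyperoxia at 6 h replicate 2 (limma, adjusted p = 0.0569) or 4 (0.0722). All 6 had positive differences, among them 0.80 for miR-132-3p (limma, adjusted p = 0.0519). The median was 0.48, with 0.52 within slide 1, 0.51 within slide 2 and an adjusted p of 5.52e-04 in fry with slide as a block. The call was lost under 7 other settings, with adjusted p from 0.0898 for quantile normalization to 0.977 without scaling. The miR-15 and miR-16 family passed fry (adjusted p = 0.0422; 0.0222 with slide as a block) and not camera (adjusted p = 0.531 with an estimated correlation), with 1 of 6 members passing, miR-322-5p, also 1 adjusted over the list alone, and medians of 0.23 over all arrays, 0.23 within slide 1 and 0.13 within slide 2. Without scaling between arrays the direction of the family turned (adjusted p = 0.875), 8 other settings with adjusted p from 0.0540 to 0.332 also ended the call, and the call was lost without normoxia at 6 h replicate 3 (0.111) or hyperoxia at 6 h replicate 2 (0.122), 3 (0.0566) or 4 (0.139).

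With slide as a block 16 miRNAs passed at 6 h, 12 of them among the 19. The difference of miR-322-5p was 0.99 within slide 1 and 0.78 within slide 2, and that of miR-146a-5p 1.03 and 1.32. Without the 3 arrays in doubt 12 passed (8 shared), and without normoxia at 6 h replicate 4 also 12. The count depended on the scaling and the background, with 2 higher and 0 lower for the percentile over all probes, 3 and 1 for quantile normalization, 0 and 1 without scaling, 0 in all for normexp (limma, where 26 entries had an unadjusted p under 0.05, against 65 in the main setting) and 4 and 0 with a floor of 1. It was 3 for the total gene signal, 6 with only the compared groups in the fit, 7 with no filter, 12 for entries detected on all 14 arrays and 51 with array weights. The median of all 302 entries itself shifted to 0.33 for all probes and to -0.29 without scaling, against 0.02 in the main setting.

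The second comparison addressed the later response. After 24 h at 85% O2, both arms of miR-140, a miRNA known from cartilage, rose: miR-140-5p 1.82-fold (1.49 to 2.23) from 6.55 ± 0.26 (SD, n = 3) to 7.42 ± 0.15 (SD, n = 4; limma, adjusted p = 0.00514; chromosome 8, 110075150 to 110075170, mm9), and miR-140-3p 1.76-fold (1.35 to 2.29). miR-31-3p rose 1.78-fold (1.46 to 2.16) from 6.42 ± 0.11 (SD, n = 3) to 7.25 ± 0.24 (SD, n = 4; limma, adjusted p = 0.00514; chromosome 4, 88556528 to 88556546). miR-21-3p rose 1.81-fold (1.43 to 2.29), while miR-21-5p from the same hairpin, among the brightest miRNAs at a log2 level of 15.02 ± 0.06 (SD, n = 3) in normoxia, differed by 0.35 (SE 0.15) and did not pass. miR-449a-5p, abundant in multiciliated airway cells, fell by 0.63 (SE 0.13) on the log2 scale, from 5.98 ± 0.10 (SD, n = 3) to 5.36 ± 0.19 (SD, n = 4; limma, adjusted p = 0.0239). The call of miR-140-3p was lost without normoxia at 24 h replicate 2 (limma, adjusted p = 0.119) or 3 (0.0696) and without hyperoxia at 24 h replicate 1 (0.0533), 2 (0.0874) or 3 (0.0791). That of miR-449a-5p was lost without normoxia at 24 h replicate 2 (0.108) or hyperoxia at 24 h replicate 2 (0.0819) or 3 (0.0791). That of miR-21-3p was lost without normoxia at 24 h replicate 2 (0.0825).

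In all, 8 miRNAs passed limma's test at 24 h, 7 higher and 1 lower. The others were miR-378b (1.65-fold, 1.43 to 1.91), miR-378-3p (1.63-fold, 1.36 to 1.94) and miR-125b-5p (1.62-fold, 1.30 to 2.01). The last call was lost without normoxia at 24 h replicate 2 (limma, adjusted p = 0.119) or 3 (0.0727) and without hyperoxia at 24 h replicate 2 (0.0819) or 3 (0.0791). miR-378b and miR-378-3p have closely similar sequences, so their probes may not be independent. For each of the 8 the arrays of the groups did not overlap, as for 43 of the 302 entries (14.2%), against 5.71% by chance. Not passing were miR-34a-5p (0.27), miR-34b-5p (-0.55; limma, adjusted p = 0.0907), miR-34c-5p (-0.30), miR-210-3p (0.26), miR-146a-5p (0.25), miR-155-5p (0.51), miR-200b-3p (-0.03), miR-200c-3p (-0.14), miR-143-3p (0.64; limma, adjusted p = 0.0907) and miR-199a-3p (0.67). Without scaling the positive differences in this list turned negative, as for 17 of the 31 miRNAs named at either time.

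The inflammation and NF-kB list passed fry at 24 h (adjusted p = 0.0101) and not camera (adjusted p = 0.320 with an estimated correlation). None of its 6 members passed and 1 passed adjusted over the list alone, while all 6 had positive differences, with a median of 0.41 over all arrays, 0.34 within slide 1 and 0.42 within slide 2. With quantile normalization miR-21-5p, miR-146a-5p and miR-146b-5p of this list turned negative. With slide as a block the adjusted p in fry was 0.00538. Without scaling between arrays the direction of this list turned (adjusted p = 0.641), 5 other settings with adjusted p from 0.191 to 1 also ended the call, and it was lost without normoxia at 24 h replicate 3 (0.0691) or hyperoxia at 24 h replicate 3 (0.0515). The mesenchymal and smooth muscle list did not pass at 24 h. All 8 tested members had positive differences, with a median of 0.66. Of them, 4 were higher when adjusted over the list alone, but none passed over all entries. In fry it gave an adjusted p of 0.112 (p = 0.0297; camera, adjusted p = 0.595 with an estimated correlation).

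At 24 h 10 miRNAs passed with slide as a block, with all 8 among them. The difference of miR-140-5p was 0.74 within slide 1 and 1.02 within slide 2, and that of miR-31-3p 0.72 and 0.94. Without the 3 arrays in doubt 7 passed (6 shared). Single arrays moved the count, to 19 without normoxia at 24 h replicate 1, to 4 without replicate 2, and to 5 without hyperoxia at 24 h replicate 2 or 3. The split was 1 higher and 0 lower for the percentile over all probes, 3 and 1 for quantile normalization, 0 and 0 without scaling (limma, where 26 entries had an unadjusted p under 0.05, against 54 in the main setting) and 1 and 0 for normexp. The count was 4 with only the compared groups in the fit or with no filter, 13 for entries detected on all 14 arrays, 15 with brightness as a covariate and 48 with array weights, and without scaling the median of all entries shifted to -0.42, against 0.08.

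**Figure D3:**
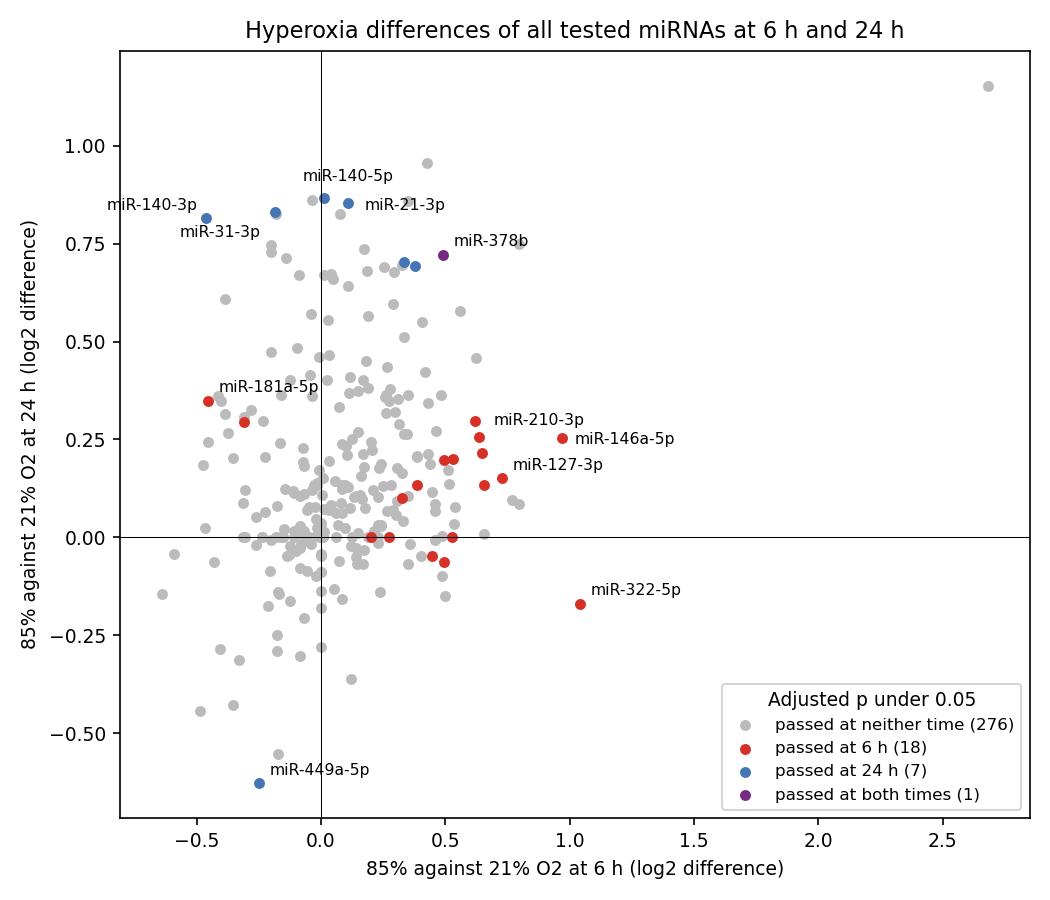
Log2 difference of 85% against 21% O2 at 6 h (horizontal) and 24 h (vertical) for the 302 tested entries, with 1 point per entry coloured by the times at which it passed limma's test. The 18 entries passing at 6 h alone and the 7 passing at 24 h alone lie mostly apart, and 1, miR-378b, passed at both times.

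Only miR-378b passed in the same direction at both times, where 0.394 were expected of independent lists of 17 and 7 rises (one-sided Fisher's exact test across miRNAs, p = 0.336). Across the 302 entries, which are not independent replicates, the log2 differences at the 2 times correlated with r = 0.249 (Spearman 0.242). The test of the difference itself found 10 miRNAs whose hyperoxia effect differed between 24 h and 6 h, 5 each way. The effect at 24 h exceeded that at 6 h by 1.27 (SE 0.24) for miR-140-3p, 1.02 (SE 0.18) for miR-31-3p, 0.86 (SE 0.18) for miR-140-5p, 0.80 (SE 0.13) for miR-181a-5p and 0.61 (SE 0.11) for miR-181b-5p on the log2 scale. The call of miR-140-5p was lost without hyperoxia at 6 h replicate 3 (limma, adjusted p = 0.0737), normoxia at 24 h replicate 2 (0.0691) or 3 (0.0584), or hyperoxia at 24 h replicate 1 (0.0566) or 3 (0.0589). miR-322-5p had the largest difference the other way, -1.21 (SE 0.21; limma, adjusted p = 0.00908), with effects of 1.04 at 6 h and -0.17 at 24 h. The remaining 4 were members of the Dlk1-Dio3 cluster, miR-377-3p (-0.56), miR-136-5p (-0.53), miR-431-5p (-0.50) and miR-541-5p (-0.20). These 4 values are no measured differences of effects, since none of the 4 was above background on any array of hyperoxia at 24 h, and miR-136-5p and miR-541-5p were at the floor on all 7 arrays of 24 h. There miR-377-3p and miR-431-5p were at the floor on 6 of 7 arrays. The 4 values mostly restate the rise at 6 h, and an effect at 24 h could not be measured, which also limits the test of the list. For that list 4 of 24 members passed and 5 adjusted over the list alone, fry gave an adjusted p of 0.00164 (0.00548 with slide as a block), and camera also passed (adjusted p = 0.030 with an estimated correlation). The medians were -0.16 over all arrays, -0.18 within slide 1 and -0.11 within slide 2. All 10 calls kept their direction within both slides and 9 passed with slide as a block, 8 of them shared. The directions within slides reuse the arrays that made the calls, and slide 2 held 5 arrays of all 4 groups, so they add little. Without the 3 arrays in doubt 7 passed (5 shared), and without normoxia at 24 h replicate 1 there were 16. The percentile over all probes gave 0 higher and 1 lower, quantile normalization 4 and 3, and no scaling and normexp 0 each (limma, where 8 and 9 entries had an unadjusted p under 0.05, against 37 in the main setting), and the call of the Dlk1-Dio3 list was lost under 9 settings.

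The comparisons of the times addressed what changed with time at each oxygen level, and since all arrays of a time shared a slide row, time and row cannot be told apart. In normoxia no miRNA passed limma's test, while 26 entries had an unadjusted p under 0.05. The smallest p-values, none passing (limma, adjusted p = 0.337), belonged to miR-23a-3p (-0.27), miR-350-3p (-0.40), miR-34b-5p (0.54), miR-1198-5p (-0.80), miR-181a-5p (-0.29), miR-205-5p (0.28), miR-203-3p (-0.41), miR-129-2-3p (-0.64), miR-23b-3p (-0.15) and miR-34c-5p (0.56). No list passed fry either (lowest adjusted p = 0.107). The Dlk1-Dio3 list, which did not pass (fry, adjusted p = 0.124), had 14 members lower and 1 higher at 24 h, with a median of -0.03. With slide as a block 1 miRNA passed and without normoxia at 24 h replicate 1 there were 14, and the percentile over all probes, which shifted the median of all entries to 0.48 from -0.04, turned the sign of miR-23a-3p, miR-23b-3p, miR-350-3p, miR-203-3p and miR-181a-5p.

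In hyperoxia 23 miRNAs passed between 6 h and 24 h, 8 higher and 15 lower at 24 h. miR-31-3p rose 2.02-fold (1.66 to 2.45) and miR-140-3p 1.96-fold (1.51 to 2.55), followed by miR-21-3p (1.63-fold), miR-140-5p (1.61-fold), miR-1839-3p (1.46-fold), miR-31-5p (1.44-fold), miR-181a-5p (1.42-fold) and miR-181b-5p (1.32-fold). miR-322-5p fell by 1.22 (SE 0.15) on the log2 scale, to 4.78 ± 0.19 (SD, n = 4; limma, adjusted p = 4.06e-04). miR-99a-5p, miR-148a-3p and miR-146a-5p had differences of -0.71, -0.64 and -0.64 and also passed. The call of miR-146a-5p was lost without any 1 of the 7 arrays, namely hyperoxia at 6 h replicate 2 (limma, adjusted p = 0.124), 3 (0.101) or 4 (0.0916) and hyperoxia at 24 h replicate 1 (0.0560), 2 (0.110), 3 (0.0525) or 4 (0.0678). That of miR-1839-3p was lost without hyperoxia at 6 h replicate 2 (0.119), 3 (0.0906) or 4 (0.103) or hyperoxia at 24 h replicate 2 (0.102) or 3 (0.103). Without hyperoxia at 6 h replicate 2 or 3, miR-21-3p (0.0730 and 0.0545) and miR-434-3p (0.0521 and 0.0514) did not pass. The other 11 were members of the Dlk1-Dio3 cluster, of whose 24 tested members 13 did not pass, and 13 passed lower adjusted over the list alone. miR-379-5p fell by 1.37, miR-300-3p by 1.17, miR-127-3p by 1.07 and miR-434-3p by 0.87 on the log2 scale. Of these 11, 7 were above background on no array of hyperoxia at 24 h, among them miR-376a-3p, at least 1.40-fold lower, miR-377-3p, at least 1.11-fold lower, miR-136-5p, at least 1.08-fold lower, and miR-431-5p, at least 1.05-fold lower. The list passed fry (adjusted p = 4.23e-06; 3.11e-05 with slide as a block; medians -0.27 within slide 1 and -0.13 within slide 2) and camera (adjusted p = 0.0143 with an estimated correlation). The miR-15 and miR-16 family passed fry (adjusted p = 0.00256; 3.54e-04 with slide as a block; medians -0.44 within slide 1 and -0.29 within slide 2), with 1 of 6 members passing and 2 adjusted over the list alone, but not camera (adjusted p = 0.179 with an estimated correlation). With slide as a block 28 passed, with all 23 among them, and the difference of miR-322-5p was -1.22 within slide 1 and -1.24 within slide 2. Without the 3 arrays in doubt 32 passed, again with all 23. The percentile over all probes left 2 higher and 2 lower, no scaling and normexp left 0 each (limma, where 14 and 13 entries had an unadjusted p under 0.05, against 57 in the main setting), and with normexp the direction of the Dlk1-Dio3 list turned (adjusted p = 0.75).

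**Figure D4:**
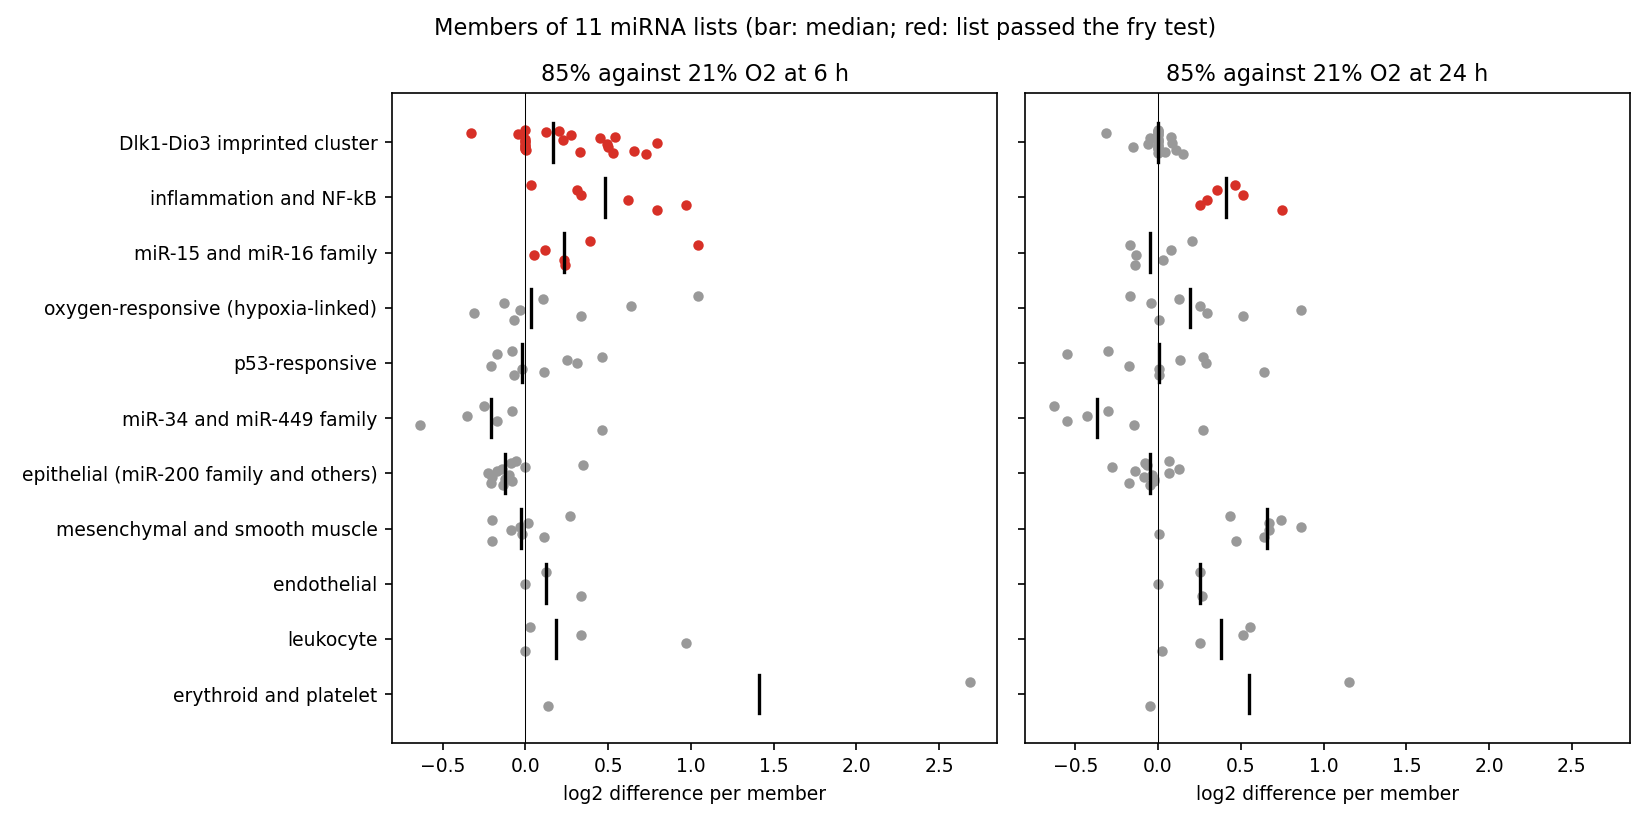
Log2 difference of 85% against 21% O2 for each tested member of 11 lists at 6 h (left) and 24 h (right). Points are members, black bars are list medians, and lists in red passed fry, namely the Dlk1-Dio3, inflammation, and miR-15 and miR-16 lists at 6 h and the inflammation list at 24 h. None of these calls passed camera with an estimated correlation. Without scaling between arrays the direction of the Dlk1-Dio3 list and of the miR-15 and miR-16 list turned at 6 h and that of the inflammation list at 24 h.

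Lists for other cell types of the lung did not pass fry at either time. The epithelial list, 13 members of the miR-200 family and others, had medians of -0.12 at 6 h (fry, adjusted p = 0.255) and -0.05 at 24 h (adjusted p = 0.539). The mesenchymal list had a median of -0.03 at 6 h (adjusted p = 0.961), with -0.04 within slide 1 and 0.32 within slide 2. The leukocyte list of 4 members, which shares miR-146a-5p and miR-155-5p with the inflammation list, had medians of 0.18 (adjusted p = 0.222) and 0.38 (adjusted p = 0.112). The endothelial list of 3 members, with miR-126-3p at the floor, had medians of 0.13 (adjusted p = 0.222) and 0.25 (adjusted p = 0.112). The striated muscle list of 3 members had medians of 0 at both times (adjusted p = 0.255 and 1). That says nothing about muscle cells, since miR-1a-3p and miR-206-3p were at the floor on all 14 arrays and miR-133b-3p on all but 1. The erythroid and platelet list held miR-144-3p and miR-451, and gave adjusted p of 0.255 and 0.891. miR-451, abundant in red blood cells, differed by 2.68 at 6 h and did not pass (limma, adjusted p = 0.179), with levels of 5.40 ± 1.56 (SD, n = 4) and 8.08 ± 1.37 (SD, n = 3).

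The oxygen-responsive list had medians of 0.04 at 6 h and 0.19 at 24 h and did not pass (fry, adjusted p = 0.255 and 0.112), although miR-322-5p and miR-210-3p rose and miR-181b-5p fell among its 8 members at 6 h. At 6 h its count was the same adjusted over the list alone. The p53-responsive list of 9 members had medians of -0.02 and 0.01 (fry, adjusted p = 0.948 and 0.891). The miR-34 and miR-449 family had medians of -0.21 at 6 h (adjusted p = 0.540) and -0.37 at 24 h (adjusted p = 0.113), with 5 of 6 members negative at each time, miR-34a-5p being the exception. Of the let-7 family all 9 members had positive differences at 6 h, 1 of which passed, with a median of 0.36 (adjusted p = 0.222), against 0.03 at 24 h (adjusted p = 0.891). The miR-17-92 and paralogue list had medians of 0.14 at each time (adjusted p = 0.316 and 0.112). Medians were 0.09 and 0.06 for the miR-29 family (adjusted p = 0.540 and 0.35), 0.08 and 0.08 for the miR-30 family (0.293 and 0.325), 0.14 and 0.07 for the miR-130 and miR-301 family (0.137 and 0.889), and -0.05 at 24 h for the miR-15 and miR-16 family (0.891). The miR-221 and miR-222 list (-0.02 and 0.10; adjusted p = 0.961 and 0.872), the miR-23, miR-27 and miR-24 clusters (0.598 and 0.891), the Sfmbt2 intron cluster of 15 members (-0.08 and 0; 0.385 and 0.891) and the 11 array-strong entries of questioned origin (-0.07 and 0.19; 0.961 and 0.539) did not pass either, nor did the Dlk1-Dio3 list at 24 h (adjusted p = 0.891). Of the 24 tested members of the Dlk1-Dio3 list, 6 had positive and 4 negative differences at 24 h. The others were at the floor with a difference of 0, so an effect on them could not be measured.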

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

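Of the tests in this part, those of mesenchymal cells were chosen only after the results they measure were seen, slide as a block was set as a choice beforehand but its use against these patterns was chosen after its results were seen, and the brightness covariate was added after the data were seen but before its own result.

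Among 98 checks of 1 array against the other 3 of its group, 10 stood apart, where chance gives 4.90. Normoxia at 6 h replicate 1 had 207 detected entries, against 267 to 279 on the other 3, and a negative control SD of 12.8 signal units, against 2.07 to 3.41. Normoxia at 6 h replicate 2, alone on its slide, stood apart for miR-136-5p (log2 level 3.71, the other 3 at the floor of 3.50), miR-31-5p (8.70, others 8.40 to 8.43), miR-34a-5p (10.36, others 10.84 to 10.90), miR-652-3p (7.63, others 7.91 to 7.96) and miR-99a-5p (8.76, others 9.22 to 9.26). In hyperoxia at 24 h, replicate 4 was apart for miR-140-3p (6.76, others 7.17 to 7.19), replicate 2 for miR-148a-3p (6.72, others 6.89 to 6.92) and replicate 3 for miR-200c-3p (9.90, others 10.05 to 10.06). For miR-136-5p the other 3 arrays were tied at the floor, so any value above the floor would stand apart. That flag, counted among the 10, therefore carries no information. The cause of these differences was not tested.

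The effect of hyperoxia differed between 24 h and 6 h for 10 miRNAs, by the test of the difference itself in limma. The differences were 1.27 for miR-140-3p (effects of -0.46 at 6 h and 0.81 at 24 h), 1.02 for miR-31-3p (-0.18 and 0.83), 0.86 for miR-140-5p (0.01 and 0.87), 0.80 for miR-181a-5p (-0.45 and 0.35) and 0.61 for miR-181b-5p (-0.31 and 0.30). The difference was -1.21 for miR-322-5p (1.04 and -0.17). For miR-377-3p (-0.56), miR-136-5p (-0.53), miR-431-5p (-0.50) and miR-541-5p (-0.20) the test passed, but none was above background on any array of hyperoxia at 24 h, so an effect at 24 h could not be measured and these values mostly restate the rise at 6 h.

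Counts were compared with those from other splits of the same arrays. No other split reached the 19 miRNAs at 6 h (highest other split 5, with 1 of 35 splits as large, the real one). The same held for the 8 at 24 h (highest other 5, 1 of 35) and the 10 for the difference of effects (highest other 5, 1 of 100 drawn). It also held for the 23 over time in hyperoxia (highest other 1, 1 of 35) and the 3 lists at 6 h in fry (highest other 1, 1 of 35). Chance is thus unlikely for these counts but not excluded, since 35 splits give no share under 0.0286 and the counts were not adjusted for their number. The other splits also mix the real groups, which can lower their counts. None of the 3 lists passed camera (adjusted p = 0.226, 0.226 and 0.531 with an estimated correlation). Other splits were as large for the 1 list at 24 h (highest other 1, 2 of 35 as large) and the 1 list of the difference of effects (highest other 3, 5 of 100 as large), so chance is not excluded there either. For time in normoxia the real count was 0 (limma, 26 at an unadjusted p under 0.05; highest other 8), so all 35 of 35 splits are as large whatever the data and nothing follows about chance.

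The first pattern weighed was the call of the Dlk1-Dio3 list in fry at 6 h. With slide as a block limma's fry gave 5.26e-05 before and an adjusted p of 5.52e-04 after adjustment over the lists, which argues against slide. With a floor of 1 the list's median was 0.53, against 0.14 for random lists matched on mean level (-0.07 to 0.34), at percentile 99.96. That met the bound written beforehand against a general lift of dim miRNAs in dimmer arrays. It cannot decide the question, since the list was picked for its call in these same data. Members of a shared transcript also vary together, and random lists do not. Camera, which compares a list with other miRNAs, did not pass (adjusted p = 0.226 with an estimated correlation). The mesenchymal list had a median of -0.0279 (SD 0.156), which met the bound set against it, that of the 6 called members at 0.47, but the verdict was set to undecided after the value was seen, because its members vary together between arrays and the 95% interval of a score per array, from -0.55 to 0.47, holds the median of all 24 members (0.16). With a floor of 1 limma's fry gave 0.0362 before and an adjusted p of 0.0950 after adjustment over the lists, and the former met the bound written beforehand against the floor, but the verdict was set to undecided after the value was seen, because 3 of the 6 called members were at the floor on all but at most 1 array of a 6 h group and only 7 of 24 members were above it on all 7 arrays. The call was also lost under other settings of scaling and background, and without scaling its direction turned. Within slide 1 the mesenchymal median was -0.04, against 0.50 for the called members. Within slide 2, which held few arrays, these were 0.32 and 0.35. A part of the floor, of scaling and background, and of mesenchymal cells in the pattern therefore stays open, beside a response of the cells to 6 h of hyperoxia.

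The second pattern weighed was the set of 8 calls at 24 h, where the hyperoxia arrays were dimmer. With brightness as a covariate their median size was 0.742 (median SE 0.146) against 0.77 (median SE 0.13) without it, and 6 of the 8 passed. miR-140-3p (0.81, SE 0.17, to 0.80, SE 0.21) and miR-449a-5p (-0.63, SE 0.13, to -0.57, SE 0.15) no longer passed (limma, adjusted p = 0.0573 each), mostly as the SE grew. All 8 passed with slide as a block, which argues against slide. The covariate values argue only against a linear trend with the percentile signal as the whole cause. Even this is weak, since the calls had been picked for their size over the SE. Other handling of brightness gave fewer calls at 24 h, 1 with the percentile over all probes, 0 without scaling, 1 with normexp and 4 with quantile normalization. A part of brightness and scaling in these calls therefore stays open. The mesenchymal list had a median of 0.656 (SD 0.264) against 0.81 for the 7 called rises. A score per array of that list differed by 0.61 at 24 h, with a 95% interval of 0.11 to 1.12 that excludes 0. The list's median over time was -0.50 in normoxia and 0.11 in hyperoxia (neither passing fry). A lower share of mesenchymal cells in normoxia than in hyperoxia at 24 h and a response of the type II cells therefore cannot be told apart. The labels name no sort that would remove such cells.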

How the results depend on the processing

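Tests chosen only after the data were seen were array brightness as a covariate, robust empirical Bayes and the fit without the 3 arrays in doubt; the other alternatives were planned. Counts below are in the order of hyperoxia at 6 h, hyperoxia at 24 h, difference of the effects, time in normoxia and time in hyperoxia, with 19, 8, 10, 0 and 23 as reported, 1 miRNA shared by the hyperoxia effects and 4 hyperoxia list tests passing. Where limma gave 0 for time in normoxia, 8 to 47 entries had an unadjusted p under 0.05, and 26 as reported. Where a value changed side or sign, the cause was not tested unless stated.

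The mean of all probes (22, 7, 11, 0 and 21), the intensity trend (19, 8, 10, 0 and 23) and robust empirical Bayes (18, 8, 10, 0 and 23) left 1 shared miRNA and 4 lists each. Over 18 settings miR-322-5p passed at 6 h in 15, and miR-146a-5p, miR-210-3p and miR-181a-5p in 12 each, and at 24 h miR-140-5p passed in 15, miR-31-3p and miR-378b in 14, miR-21-3p in 13 and miR-449a-5p in 12. Fewer were passed at 6 h by miR-148a-3p (9), miR-99a-5p, miR-652-3p and miR-378b (8 each), miR-127-3p and let-7i-5p (7 each) and miR-181b-5p (4), of 17 settings by miR-136-5p (10), miR-377-3p (8) and miR-146b-5p (7), and at 24 h by miR-140-3p (10), miR-125b-5p (8) and miR-378-3p (11 of 17). For the difference of effects the named miRNAs passed in 5 of 16 (miR-377-3p) to 14 of 17 (miR-181a-5p). Camera with an estimated correlation passed 0 of the hyperoxia list tests at 6 h and 24 h, while it passed the Dlk1-Dio3 list for the difference of effects and for time in hyperoxia.

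The percentile over all probes gave 2, 1, 1, 0 and 4 miRNAs, 0 shared and 0 lists. Among the 31 miRNAs named at either time, it turned the sign of 8 at 6 h. These were miR-181b-5p (0.0994), the only called one, and miR-34b-5p (0.24), miR-34c-5p (0.33), miR-200b-3p (0.31), miR-200c-3p (0.24), miR-199a-3p (0.32), miR-31-3p (0.23) and miR-449a-5p (0.16). For time in normoxia it turned miR-23a-3p (0.52), miR-350-3p (0.39), miR-181a-5p (0.49), miR-203-3p (0.38) and miR-23b-3p (0.63). Quantile normalization gave 4, 4, 7, 0 and 22, with 0 shared and 1 list. It turned miR-21-5p (-0.06) and miR-140-5p (-0.05) at 6 h. At 24 h it turned miR-210-3p (-0.05), miR-21-5p (-0.09), miR-146a-5p (-0.07), miR-146b-5p (-0.07) and miR-148a-3p (-0.06), none of them called at that time. No scaling gave 1, 0, 0, 1 and 0, with 0 shared and 0 lists. Of the 31 miRNAs named at either time, no scaling turned the sign of 8 at 6 h, none of them called and miR-34a-5p (-0.02) among them, and of 17 at 24 h. At 24 h these were miR-378-3p (-0.21), miR-125b-5p (-0.0017), miR-34a-5p (-0.42), miR-210-3p (-0.44), let-7i-5p (-0.48), miR-146b-5p (-0.47), miR-148a-3p (-0.49), miR-652-3p (-0.49), miR-181b-5p (-0.40), miR-181a-5p (-0.34), miR-21-5p (-0.34), miR-146a-5p (-0.44), miR-155-5p (-0.18), miR-143-3p (-0.05), miR-199a-3p (-0.02), miR-127-3p (-0.56) and miR-99a-5p (-0.56), where the median of all entries shifted to -0.42. It also turned the miR-15 and miR-16 list (adjusted p = 0.875) and the Dlk1-Dio3 list (0.893) at 6 h and the inflammation list at 24 h (0.641).

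Normexp background gave 0, 1, 0, 0 and 0, with 0 shared and 3 lists, and turned miR-449a-5p (0.0231) and miR-322-5p (0.24) at 24 h, and over time in hyperoxia miR-376a-3p (0.0221), miR-434-3p (0.0425), miR-377-3p (0.0745) and the Dlk1-Dio3 list (adjusted p = 0.75). Its offset of 50 was added before scaling, so by construction it compresses differences of dim miRNAs. It also lifts them more on dimmer arrays, which can turn a sign. The total gene signal and the series matrix values each gave 3 at 6 h, 0 shared and 1 list. A floor of 1 gave 4 at 6 h, 4 for the difference of effects and 0 shared.

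Only entries detected on all 14 arrays gave 12, 13, 6, 0 and 13, with 2 shared, from fewer entries tested. No filter gave 7, 4, 3, 0 and 17, with 0 shared and 0 lists, from more entries tested. Array weights gave 51, 48, 14, 0 and 60, with 12 shared and 14 lists. Only the compared groups in the fit gave 6 at 6 h and 4 at 24 h, with fewer arrays behind the spread, and an adjusted p of 0.0214 for the striated muscle list at 24 h, which carries no information because all 3 members were at the floor on every 24 h array. The difference of effects needs all 4 groups and has no value under that setting. Brightness as a covariate gave 15 at 24 h and 2 shared. Without the 3 arrays in doubt there were 12 at 6 h, 7 at 24 h, 7 for the difference of effects, 1 for time in normoxia and 32 for time in hyperoxia, with 0 shared.

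Slide as a block gave 16, 10, 9, 1 and 28, with 2 shared. The replicate number as a block gave 24, 17, 11, 1 and 24, with 2 shared. Deviations of equal numbers correlated at -0.116, -0.15 and -0.103 at 6 h and at -0.195, -0.405 and -0.230 at 24 h, and no array matched its own number best, so the numbers were not taken to pair samples.

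Leaving out each array in turn gave 12 to 20 miRNAs at 6 h, 4 to 19 at 24 h, 9 to 16 for the difference of effects, 0 to 14 for time in normoxia and 19 to 27 for time in hyperoxia, with 1 to 3 shared and 2 to 9 lists. The extremes were 12 without normoxia at 6 h replicate 4, and 19, 16 and 14 (24 h, difference of effects, time in normoxia) without normoxia at 24 h replicate 1. At 24 h there were 4 without normoxia at 24 h replicate 2 and 5 without hyperoxia at 24 h replicate 2 or 3. miR-322-5p, miR-146a-5p, miR-210-3p and miR-181a-5p at 6 h and miR-140-5p, miR-31-3p, miR-378b and miR-378-3p at 24 h passed in all 7 of these fits. Fewer were passed at 6 h by miR-127-3p and miR-181b-5p (1 of 7 each), let-7i-5p (3), miR-148a-3p (4), miR-146b-5p (5) and miR-99a-5p (6), and at 24 h by miR-140-3p (2), miR-125b-5p (3), miR-449a-5p (4) and miR-21-3p (6). Over time in hyperoxia miR-146a-5p passed in 0 of 7 and in 10 of 18 settings, miR-1839-3p in 2 of 7, and miR-21-3p and miR-434-3p in 5 of 7. The difference in detected entries ranged from -3 (without normoxia at 6 h replicate 1) to 24 at 6 h, and for time in normoxia from -6 (without normoxia at 24 h replicate 2) to 38.5, with -2.67 without normoxia at 6 h replicate 1. Signal over background limits the dim miRNAs, since 116 of the 302 entries were at the floor on at least 1 array.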

Other observations

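The tests in this part, of the effect averaged over both times and of ciliated cells, were all chosen only after the data were seen.

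With the hyperoxia effect averaged over 6 h and 24 h, 39 miRNAs passed limma's test, 37 higher and 2 lower, and 82 entries had an unadjusted p under 0.05. miR-378b rose by 0.61 (SE 0.067, adjusted p = 5.76e-04), miR-132-3p, a miRNA induced by CREB, by 0.77 (SE 0.15, adjusted p = 0.0111), miR-146a-5p by 0.61 (SE 0.12), miR-224-5p by 0.54 (SE 0.12), miR-125b-5p by 0.53 (SE 0.10), miR-210-3p by 0.45 (SE 0.081, adjusted p = 0.0108) and miR-34a-5p by 0.37 (SE 0.092, adjusted p = 0.0259) on the log2 scale. miR-449a-5p fell by 0.44 (SE 0.089) and miR-182-5p by 0.19 (SE 0.043). With the mean of all probes the rise of miR-378b was 0.30, against 0.61 for its brightest probe. Lists higher in fry were inflammation (adjusted p = 1.67e-04), Dlk1-Dio3 (0.00111), leukocyte (0.0240), oxygen-responsive (0.0406), endothelial (0.0406), miR-17-92 (0.0430) and miR-15 and miR-16 (0.0491), and in camera none of the 7 passed (lowest adjusted p = 0.210 with an estimated correlation). In the endothelial list no member passed, and miR-126-3p was at the floor, so no change in it could be measured. In the leukocyte list only miR-146a-5p passed, which is shared with the inflammation list. miR-142-3p, detected on only 4 arrays, differed by 0.01, which is no measure of its change. The calls of both lists therefore say little about endothelial cells or leukocytes. The counts depended on the scaling and the background, with 2 higher and 0 lower for the percentile over all probes, 2 and 3 for quantile normalization, 0 and 3 without scaling, 9 and 0 for normexp, 3 and 1 for the total gene signal or the series matrix values, 30 and 1 for the mean of all probes, 23 and 2 with a floor of 1, 34 and 3 with slide as a block and 77 and 10 with array weights. Without scaling the median of all entries shifted to -0.31, against 0.08, and 33 of the 39 turned, among them miR-210-3p (-0.14), miR-34a-5p (-0.22), miR-224-5p (-0.05) and miR-125b-5p (-0.05), and with normexp miR-449a-5p turned (0.04). Of the 7 lists none passed higher with any of the first 3 scalings, and 5 did with normexp. The total gene signal, the series matrix values and the mean of all probes each kept 2. A floor of 1 kept 3, slide as a block 6 and array weights 7. An average does not show a change at both times, since 7 of the 10 miRNAs whose effects differed between the times also passed it.

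The third pattern weighed was that miR-34b-5p, miR-34b-3p, miR-34c-5p, miR-34c-3p and miR-449a-5p, abundant in multiciliated cells, had negative differences in hyperoxia at both times, although only miR-449a-5p at 24 h passed (at 6 h miR-34c-5p was at -0.08, at 24 h miR-34b-3p at -0.14). Averaged over both times, with a median of -0.39 (SD 0.0945 between members), limma's fry for these 5 gave 0.00458, unadjusted, which mostly restates what was noticed, and it gave 0.100 at 6 h and 0.00869 at 24 h, while the miR-34 and miR-449 list with miR-34a-5p did not pass (adjusted p = 0.107; camera, adjusted p = 0.372 with an estimated correlation). Fewer ciliated cells in the hyperoxia samples and a lower level of these miRNAs per cell cannot be told apart, and the values do not decide whether either took place. The brightest on the arrays, miR-34b-5p, which signals of different probes do not show to be the most abundant, was at 10.15 ± 0.21 (SD, n = 3) in normoxia and 9.59 ± 0.26 (SD, n = 4) in hyperoxia at 24 h, and the labels name no sort that would remove ciliated cells. With normexp background miR-449a-5p turned to 0.02 at 24 h, with the percentile over all probes miR-34b-5p (0.24), miR-34c-5p (0.33) and miR-449a-5p (0.16) turned at 6 h, and how many of the 5 are made by type II cells themselves is not given in the sources used here.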
